A study of Mus musculus with 8 samples.

How the data were processed

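Small RNA libraries of mouse embryonic stem cells were analysed: wild type E14 (A and B), Ago2 knockout lines 1 and 2, and an AGO1-expressing line made from the knockout without (A and B) and with doxycycline (A and B), 8 libraries in 4 groups of 2. Per the labels' protocols, cells grew on gelatine in 15% serum with 100 U/mL LIF, the AGO1 line was kept in puromycin at 2 µg/mL, induction used doxycycline at 1 µg/mL, and libraries were made from 1 µg of total RNA with an Illumina TruSeq small RNA kit. The labels do not say whether A and B are separate cultures. The deposited table holds whole-number counts per mature miRNA, without normalization. Bowtie and the mm10 build are named in the submitters' processing notes, without a version. Adapter trimming, mismatches, reads with several matches and the miRNA annotation release are not given in the sources used here. The table has 2 header lines; in the second, 1 name did not match the first (both are wild type libraries), and the first line was used.

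Totals of counts ranged from 163467 to 1326638 per library. A count of 0 was read as allowing up to 3 counts, which is 2.26 to 18.4 CPM by library, and ratios of counts of 3 or fewer are given with 95% exact binomial intervals. Such floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Of 1915 miRNAs, 901 had no count. The 475 that passed edgeR's filterByExpr held 99.9% of counts and were tested. Analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. CPM values were computed here from library totals multiplied by edgeR's TMM factors.

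Each comparison used edgeR's quasi-likelihood F test (2-sided) on the counts with TMM factors (0.881 to 1.22) in 1 fit of the 8 libraries with 4 groups, which leaves 4 residual degrees of freedom, and Benjamini-Hochberg adjustment over the 475 miRNAs within each of the 4 comparisons. A call is an adjusted p under 0.05. The common biological coefficient of variation was 0.244. In simulated counts for knockout against wild type, run on 454 miRNAs, 32 of 99 miRNAs changed 2-fold and 85 of 95 changed 4-fold were called, with 3 false calls among 260 unchanged. For doxycycline, run on 447 miRNAs, 41 of 98 and 87 of 95 were called, with 6 false calls among 254. For the arm ratio in knockout against wild type, run on 139 hairpins, 24 of 40 changed 4-fold were called, with 0 false calls by edgeR among 99. All simulated groups had the same spread per miRNA. The real knockout libraries differed more from each other than those of other groups, so these rates may not hold for the knockout comparison.

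Before the data were examined, 22 lists were fixed by name: the miR-290-295, miR-302-367, miR-17-92 with paralogs, miR-183-96-182, Dlk1-Dio3, Sfmbt2 and X-linked germline clusters; the let-7, miR-200, miR-15 and miR-16, miR-34 and miR-449, miR-130 and miR-301, miR-148 and miR-152, miR-99, miR-100 and miR-125 and miR-181 families; miRNAs of AGO2-slicer-dependent and of non-canonical biogenesis; and markers of muscle, neural, blood, fibroblast, and liver and endoderm cells. The minor arms, each hairpin's arm with the lower mean CPM over the 8 libraries, formed 1 more list. The 21 lists with at least 3 measured members were tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. The comparisons, tests and alternatives were also chosen before the data were examined, except where the text says otherwise.

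Named miRNAs follow a rule fixed at the same time. For each comparison it takes the 8 with the largest rise and the 8 with the largest fall among calls with a mean CPM of at least 20 and non-overlapping groups. It adds the 5 most abundant, the 2 members of each list with the smallest adjusted p in the first 2 comparisons, and miR-451a and miR-486. From these 83 miRNAs the text gives those that matter most. Names outside the rule were chosen after their values were seen: single hairpins of the arm ratio, further members named in lists, and the miRNAs given for their spread within a group. The arm ratio was tested in edgeR with both arms of each library as columns, each library as a term, and arm by group as the effect. Coordinates come from GENCODE vM21 on GRCm38, where 79 of the 83 named miRNAs have a gene.

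Alternatives were DESeq2 size factors, library totals without TMM factors, the DESeq2 Wald test, no abundance filter, a mean CPM of at least 20, only the 2 groups compared, a log2 fold change of at least 1, each library left out, and the letters A and B as a replicate block. Added after the data were seen were a fit without the 2 shallowest libraries, counts thinned to the smallest library, the arm ratio, the minor arm set by wild type or knockout counts, 1 wild type library for each comparison, the overlaps and all arm ratio counts with each library left out, and the 2 differences of medians in the closing section. Correlations of log2 fold changes run across miRNAs and carry no p. Shared wild type libraries were examined with 100 simulations of unchanged groups (seed 20). Sequencing batches are not given in the sources used here, so none was modelled.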

Results

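Small RNA from mouse embryonic stem cells was sequenced in 8 libraries that form 4 groups of 2. The wild type cells are E14, a pluripotent line derived from a 129/Ola blastocyst. The Ago2 knockout cells lack AGO2, an Argonaute protein that holds miRNAs on their target RNAs and the one mammalian family member known for strong slicing of targets. The other 2 groups are an AGO1 line made from knockout cells, without and with doxycycline at 1 µg/mL, the drug that switches on its AGO1 transgene. Counts of mature miRNAs summed to 949620 and 1115712 in wild type A and B, 359099 and 163467 in knockout lines 1 and 2, 736895 and 292895 in the uninduced AGO1 line A and B, and 1326638 and 1117435 in the induced line A and B. Of 1915 miRNAs listed, 542 to 780 had a count in any 1 library. The 10 most abundant miRNAs took 58.7 to 63.0% of each library.

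Abundance is given in CPM (counts scaled to a common library total), as mean ± SD (n = 2), and changes as edgeR log2 fold changes ± SE. The edgeR test returns no SE. It was derived here as the absolute log2 fold change divided by the square root of the F statistic, and is approximate. Abundances and changes are both relative: a rise or fall of all miRNAs together would not appear in them. The highest level that a count of 0 allows (3 counts) was 2.26 to 18.4 CPM, depending on the library. Ago2 mRNA and AGO protein were not analysed here, so the genotypes rest on the labels. miR-451a, whose maturation needs slicing by AGO2, had 0 counts in all 8 libraries. miR-486a-5p, also matured by AGO2 slicing in red blood cells, had 35 and 72 counts in wild type and 9 and 14 in the knockout lines. Its log2 fold change was -0.38 ± 0.50 (edgeR adjusted p = 0.532). For the near-identical miR-486b-5p, with 40 and 65 counts in wild type and 7 and 24 in the knockout lines, it was 0.16 ± 0.63 (edgeR adjusted p = 0.835). Reads of this pair are hard to assign to 1 gene.

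The knockout was compared with wild type to ask how miRNA abundance differs without AGO2. miR-301a-3p, of the miR-130 and miR-301 seed family, fell from 3784 ± 202 CPM in wild type to 71.4 ± 5.84 CPM in the knockout (n = 2 each), a 53.4-fold drop by edgeR. miR-431-5p, from the imprinted Dlk1-Dio3 region, fell from 6818 ± 859.7 to 397 ± 34.3 CPM. miR-143-3p, best known from smooth muscle and connective tissue, fell from 3419.7 ± 386 to 349 ± 2.74 CPM. In the opposite direction, miR-142a-3p, typical of blood cells, rose from 44.0 ± 21.9 to 443 ± 143 CPM, and miR-375-3p, typical of pancreatic islets, from 42.8 ± 3.28 to 331 ± 162 CPM. miR-295-3p, the main product of the miR-290-295 cluster of pluripotent cells, stood at 160536 ± 22459.9 and 140073 ± 8789.7 CPM, a log2 fold change of -0.20 ± 0.15 (edgeR adjusted p = 0.266).

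Of 475 miRNAs tested, 274 differed at an adjusted p under 0.05 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 121 higher and 153 lower in the knockout. The Spearman correlation between the 2 libraries was 0.879 in the knockout and 0.972 in wild type. The spread in the test was pooled over the 4 groups. Of these, only the knockout pairs 2 separate lines, so the pooled spread may understate how far lines differ. At least 2-fold changes made up 105 of the higher and 132 of the lower ones. The log2 fold change was -5.74 ± 0.23 for miR-301a-3p (edgeR adjusted p = 6.98e-08) and -5.42 ± 0.31 for miR-301b-3p (edgeR adjusted p = 5.89e-07), 2 miRNAs whose reads are nearly alike. The corresponding values were -4.10 ± 0.22 for miR-431-5p (edgeR adjusted p = 5.43e-07), -3.99 ± 0.23 for miR-103-3p (edgeR adjusted p = 5.89e-07) and -3.29 ± 0.20 for miR-143-3p (edgeR adjusted p = 8.05e-07). Those that rose furthest included miR-19b-1-5p (4.02 ± 0.59, edgeR adjusted p = 0.000361), miR-195a-3p (3.39 ± 0.40, edgeR adjusted p = 8.75e-05), miR-142a-3p (3.29 ± 0.38, edgeR adjusted p = 8.56e-05) and miR-25-5p (3.27 ± 0.37, edgeR adjusted p = 7.89e-05). Without TMM factors the median over all tested miRNAs moved from -0.13 to 0.16, and the split of the 266 calls became 155 higher and 111 lower. With only the 2 groups in the fit 194 were called, 91 higher and 103 lower. DESeq2 called 218, with 105 higher and 113 lower. Without wild type A 104 were higher and 91 lower, without wild type B 83 and 127, without knockout 1 118 and 142, and with every library thinned to the smallest 73 and 94. Without knockout 2 the total was 274, of which 122 were higher.

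On mouse build GRCm38 (mm10) with GENCODE vM21, miR-301a lies in an intron of Ska2 (chromosome 11, 87113004 to 87113089), and miR-301b in an intron of 2610318N02Rik (chromosome 16, 17124400 to 17124496). miR-431 (chromosome 12, 109590447 to 109590537) lies opposite an exon of Rtl1. miR-103 has 2 genes, in introns of Pank3 (chromosome 11, 35782396 to 35782481) and Pank2 (chromosome 2, 131288052 to 131288137). No other annotated gene overlaps miR-143 (chromosome 18, 61649196 to 61649258) or miR-375 (chromosome 1, 74900658 to 74900721). miR-142a lies in an intron of Mir142hg (chromosome 11, 87756864 to 87756927), and miR-25 overlaps an exon of Mcm7 (chromosome 5, 138165321 to 138165404).

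The Dlk1-Dio3 imprinted cluster, a large miRNA region expressed from the maternal chromosome, was lower as a list. Of its 79 measured members 48 fell and 10 rose (10 up and 48 down adjusted over the list alone), with a median log2 fold change of -1.36, or -1.25 with 3 members without counts in a group placed at their bound (camera adjusted p = 0.000216, and adjusted p = 0.662 with an estimated correlation). miR-433-3p (-4.17 ± 0.33, edgeR adjusted p = 6.39e-06) and miR-666-5p (-3.86 ± 0.25, edgeR adjusted p = 1.45e-06) were among those that fell. miR-412-5p had 0 counts in both knockout libraries against 98 in wild type, at least 10-fold lower by a floor of 3 counts over the group. The measured members span 184 kb of chromosome 12, from 109563692 to 109747960. As a share of all counts, the 109 listed members held 24.0 ± 0.20% in wild type and 19.3 ± 3.18% in the knockout. They held 23.9 ± 1.00% in the uninduced and 27.9 ± 1.07% in the induced AGO1 line (SD, n = 2). miR-411-5p of this cluster rose by 0.64 ± 0.17 (edgeR adjusted p = 0.00905), a call lost without wild type B (0.57, edgeR adjusted p = 0.0673). miR-127-3p fell by 0.65 on the log2 scale (edgeR adjusted p = 0.0147), and that call was lost without wild type A (edgeR adjusted p = 0.181) and without knockout 2 (edgeR adjusted p = 0.123).

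**Figure D1:**
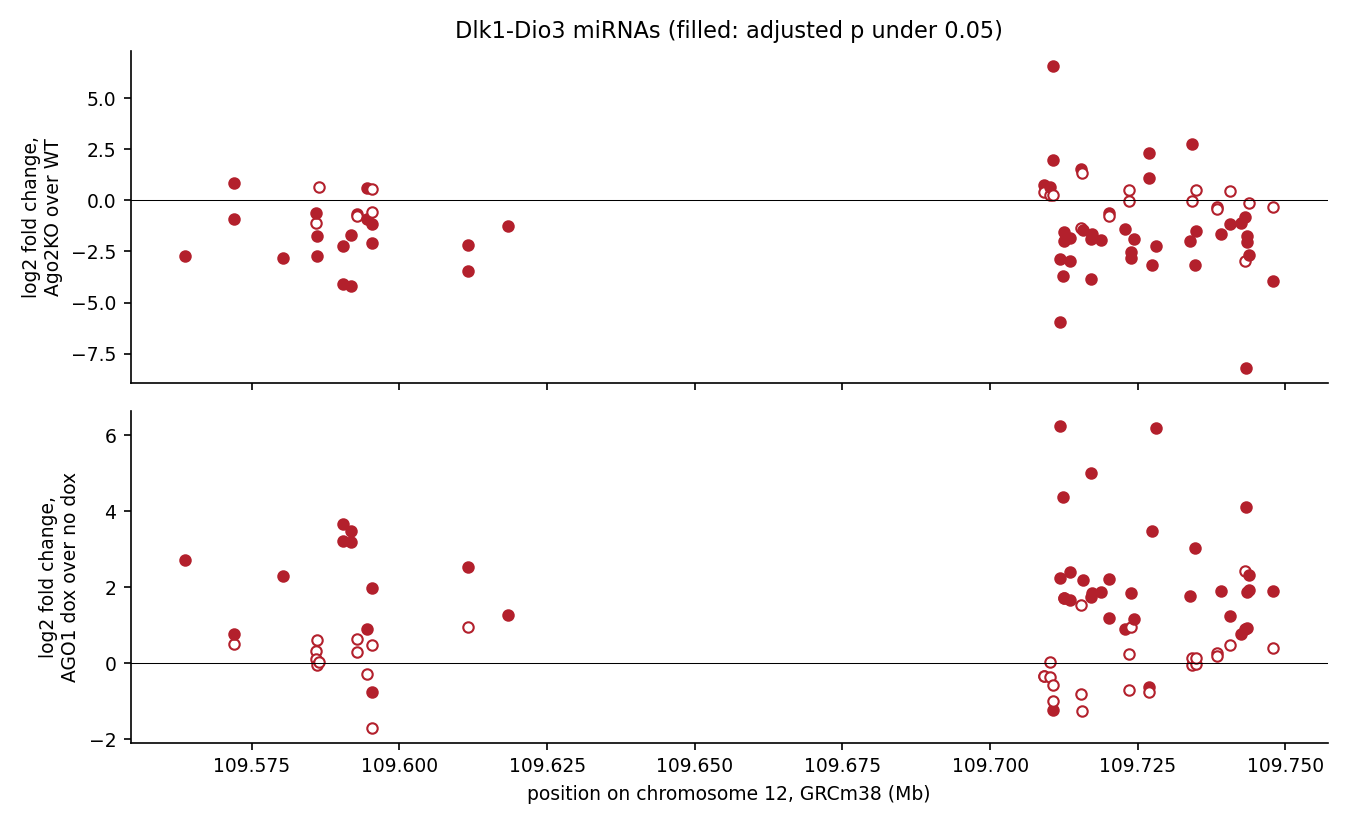
Log2 fold changes of the 79 measured miRNAs of the Dlk1-Dio3 cluster by position on chromosome 12 (GRCm38, Mb), for knockout over wild type (top) and AGO1 line with over without doxycycline (bottom); each point is 1 miRNA, filled where the edgeR adjusted p is under 0.05. In the top panel 48 filled points lie below 0 and 10 above; in the bottom panel 42 lie above 0 and 3 below.

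The let-7 family, which promotes differentiation and is held low in pluripotent cells by LIN28, also fell: 7 of 11 measured members were lower and 0 higher (0 up and 7 down adjusted over the list alone), with a median of -1.79 (camera adjusted p = 0.0270, and adjusted p = 0.662 with an estimated correlation). let-7e-5p fell from 116 ± 4.22 to 11.3 ± 5.40 CPM (-3.49 ± 0.44, edgeR adjusted p = 0.000123), and let-7f-5p from 812 ± 145 to 195 ± 76.5 CPM (-2.02 ± 0.28, edgeR adjusted p = 0.000269). The knockout values of let-7e-5p, 7.48 and 15.1 CPM in lines 1 and 2, rest on few counts. Of the 8 measured members of the miR-130 and miR-301 family 5 fell (miR-130a-3p and both arms of miR-301a and miR-301b) and miR-130b-5p rose (1 up and 5 down adjusted over the list alone; median -1.93, camera adjusted p = 0.0478, and adjusted p = 0.662 with an estimated correlation). The list's call was lost without wild type A (camera adjusted p = 0.133) or B (0.0855), knockout 1 (0.0638) or 2 (0.126), and induced AGO1 line A (0.0822) or B (0.0737), and also without TMM factors (camera adjusted p = 0.117). A single call was lost (edgeR adjusted p in parentheses) for miR-301b-5p without wild type A (0.0656) or knockout 1 (0.133). The let-7 members differ by few bases, so reads can be shared among them.

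The lists that rose were the Sfmbt2 repeat cluster, the miR-15 and miR-16 family and the blood cell markers. In the Sfmbt2 list, which takes miR-297, miR-466, miR-467 and miR-669 copies by name after a rodent-specific array in that gene (miR-467h lies on chromosome 9 instead), 20 of 41 measured members rose and 3 fell, miR-297b-5p, miR-466o-3p and miR-669c-5p (20 up and 3 down adjusted over the list alone; median 1.08, camera adjusted p = 0.00148, and adjusted p = 0.699 with an estimated correlation). miR-467c-5p rose by 1.69 ± 0.26 (edgeR adjusted p = 0.000556), and the near-identical copies make single members of this cluster uncertain. The 3 falls were lost (edgeR adjusted p in parentheses) for miR-297b-5p without wild type B (below the abundance filter) or knockout 1 (0.307), miR-466o-3p without wild type A (0.0677), wild type B (0.187) or knockout 1 (0.290), and miR-669c-5p without wild type B (0.0605) or knockout 1 (0.0753). The miR-15 and miR-16 family, known for restraining the cell cycle, was listed with both arms of its hairpins. Those that rose included miR-195a-3p (3.39) and miR-15a-3p (1.30, edgeR adjusted p = 0.0443) as well as miR-195a-5p (1.56) and miR-322-5p (1.47). The arms miR-15a-5p (0.16) and miR-15b-5p (-0.36) were not called. Of the 12 listed, 6 rose and 0 fell (5 up and 0 down adjusted over the list alone; median 1.20, camera adjusted p = 0.0478, and adjusted p = 0.662 with an estimated correlation). That call was lost without wild type B (camera adjusted p = 0.0799) or knockout 1 (camera adjusted p = 0.170). Of 5 measured blood cell markers 4 rose, namely both arms of miR-142a and of miR-150, and 0 fell (4 up and 1 down adjusted over the list alone; median 2.77, camera adjusted p = 0.0157, and adjusted p = 0.662 with an estimated correlation). All 5 had counts in wild type too, and the list's share of all counts was 0.180% in wild type and 0.724% in the knockout.

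Other lists were not called by camera, though members changed. Without knockout 2, however, the miR-302-367 (camera adjusted p = 0.00823) and X-linked germline lists (camera adjusted p = 0.00176) were called as higher. The miR-290-295 cluster, the main miRNA locus of pluripotent cells, had 8 of 18 members lower and 3 higher, miR-290a-3p, miR-290b-5p and miR-295-5p (3 up and 8 down adjusted over the list alone; camera adjusted p = 0.892). In the miR-17-92 cluster and its paralogs, which promote proliferation, 10 of 26 were lower and 8 higher (8 up and 10 down adjusted over the list alone; camera adjusted p = 0.892). Its median was -0.21 but its mean 0.18, and the median became 0.10 without TMM factors. Of 5 measured members of the miR-302-367 cluster, another pluripotency locus, 3 rose, miR-302d-3p, miR-302d-5p and miR-367-3p (3 up and 0 down adjusted over the list alone; camera adjusted p = 0.157). miR-302d-5p had 14 counts in the knockout and 3 in wild type, a ratio of 15.2 (95% counting interval 4.24 to 82.4). The miR-34 and miR-449 family, whose miR-34 genes are targets of p53, had 3 of 6 higher, both arms of miR-34a and miR-34c-5p (3 up and 0 down adjusted over the list alone; camera adjusted p = 0.118), with miR-34a-5p at 1.07 ± 0.24 (edgeR adjusted p = 0.00420). In the miR-148 and miR-152 family 5 of 6 fell (0 up and 5 down adjusted over the list alone; camera adjusted p = 0.278), with miR-148b-3p at -2.31 ± 0.27 (edgeR adjusted p = 8.75e-05). With 1 library left out, calls among those named were lost (edgeR adjusted p in parentheses) for miR-290a-3p without wild type B (0.155), miR-290b-5p without wild type B (0.0703) or knockout 2 (0.0809), miR-302d-3p without knockout 1 (0.393), miR-302d-5p without wild type B (0.0603) or knockout 1 (0.188), miR-367-3p without wild type A (0.0925), wild type B (0.0508) or knockout 1 (0.689), and miR-34a-3p without wild type B (0.149) or knockout 1 (0.418). In the miR-148 and miR-152 family they were lost for miR-148a-3p without wild type A (0.316), wild type B (0.110), knockout 1 (0.0625) or knockout 2 (0.226), miR-148b-5p without wild type A (0.213) or knockout 1 (0.0744), miR-152-3p without wild type A (0.101), wild type B (0.0939) or knockout 1 (0.363), and miR-152-5p without wild type A (0.0811), wild type B (0.126) or knockout 1 (0.123).

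In the miR-183-96-182 cluster, known from sensory cells and abundant in these cells, 3 of 6 members fell (miR-182-5p and both arms of miR-183) while miR-182-3p and miR-96-3p rose (2 up and 3 down adjusted over the list alone; camera adjusted p = 0.892), with a median of -0.50 and a mean of 0.01. Its abundant member miR-182-5p fell from 177159 ± 7229.8 to 104590.0 ± 29.6 CPM (-0.76 ± 0.15, edgeR adjusted p = 0.00170). The miR-99, miR-100 and miR-125 group had 4 of 7 higher (miR-125a-5p, miR-125b-5p, miR-125b-1-3p and miR-125b-2-3p) and both arms of miR-99b lower (5 up and 2 down adjusted over the list alone), with miR-99b-5p at -2.02 ± 0.19 (edgeR adjusted p = 1.7e-05). Of 5 miR-181 members, miR-181a-5p, miR-181b-5p and miR-181c-3p rose while miR-181c-5p and miR-181d-5p fell (3 up and 2 down adjusted over the list alone). In the miR-200 family, a keeper of epithelial identity, 1 of 8 fell (0 up and 0 down adjusted over the list alone). This was miR-429-3p (-0.74 ± 0.24, edgeR adjusted p = 0.0230), whose call was lost without wild type A (edgeR adjusted p = 0.258) and without knockout 2 (edgeR adjusted p = 0.0924). Among 6 miRNAs of non-canonical biogenesis 1 fell (0 up and 1 down adjusted over the list alone), miR-1981-5p, with 3 counts against 162 and a ratio of 16.6 (95% counting interval 5.58 to 81.3). In the X-linked germline cluster 3 of 10 rose, miR-465a-3p, miR-465c-3p and miR-871-5p (0 up and 0 down adjusted over the list alone). With 1 library left out, calls were lost (edgeR adjusted p in parentheses) for miR-125b-1-3p without wild type B (0.159) or knockout 2 (0.0876), miR-125b-2-3p without wild type A (0.0562), knockout 1 (0.0883) or knockout 2 (0.0548), miR-99b-3p without knockout 1 (0.0710), miR-181a-5p without wild type A (0.0732) or knockout 1 (log2 fold change -0.51, 0.677), miR-181b-5p without knockout 1 (0.243), and miR-181d-5p without wild type A (0.115). In the X-linked cluster they were lost for miR-465a-3p without wild type A (0.0738), wild type B (0.106) or knockout 1 (0.826), miR-465c-3p without wild type B (0.159) or knockout 1 (0.900), and miR-871-5p without wild type A (0.108), wild type B (0.0817) or knockout 1 (log2 fold change -5.56, 0.145).

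Neural markers had 3 of 10 higher (miR-124-5p, miR-129-1-3p and miR-219a-1-3p) and miR-128-3p and miR-138-5p lower (3 up and 2 down adjusted over the list alone), with a median of -0.09, a mean of 0.13, and a median of 0.20 without TMM factors. Calls were lost (edgeR adjusted p in parentheses) for miR-124-5p without wild type B (0.0547), and miR-129-1-3p without wild type A (0.0530), wild type B (0.141) or knockout 1 (log2 fold change -0.16, 0.945). Fibroblast markers had 1 of 7 higher, miR-21a-3p, and 1 lower, miR-143-3p (1 up and 1 down adjusted over the list alone). The call for miR-21a-3p (1.70 ± 0.48, edgeR adjusted p = 0.0131) was lost without wild type A (edgeR adjusted p = 0.0529), wild type B (edgeR adjusted p = 0.0662) or knockout 2 (0.47, edgeR adjusted p = 0.172). Liver and endoderm markers had 1 of 3 higher, miR-375-3p (1 up and 0 down adjusted over the list alone). Of the muscle markers 0 passed the abundance filter, and of the 2 measured miRNAs that depend on AGO2 slicing 0 were called (0 up and 0 down adjusted over the list alone). For the lists without a camera value given, its adjusted p lay between 0.269 and 0.909. With an estimated correlation, camera called 0 of the lists in any of the 4 comparisons.

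The AGO1 line was compared with and without doxycycline to ask which miRNAs move when AGO1 is induced in cells without AGO2. miR-666-5p, a Dlk1-Dio3 miRNA, rose 31.9-fold by edgeR, from 29.9 ± 4.83 CPM without to 987 ± 82.9 CPM with doxycycline (n = 2 each). miR-301a-3p rose from 78.7 ± 5.75 to 1240.1 ± 115 CPM, and miR-431-5p from 579 ± 61.2 to 5341 ± 659 CPM. miR-298-5p, from a cluster near the imprinted Nespas-Gnas locus (GRCm38 chromosome 2, 174267504 to 174267585), rose from 2001 ± 91.3 to 30986 ± 1459 CPM. miR-375-3p fell from 359.9 ± 15.3 to 91.0 ± 4.52 CPM.

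With doxycycline 100 of the 475 miRNAs were higher and 36 lower by the edgeR quasi-likelihood test, 84 and 28 of them by at least 2-fold. The rise of miR-666-5p had an edgeR adjusted p = 5.55e-07. The log2 fold changes were 4.84 ± 0.34 for miR-301b-3p (edgeR adjusted p = 4.02e-06), 3.99 ± 0.21 for miR-301a-3p (edgeR adjusted p = 5.55e-07), 3.95 ± 0.34 for miR-298-5p (edgeR adjusted p = 1.55e-05) and -1.98 ± 0.33 for miR-375-3p (edgeR adjusted p = 0.00166). In the uninduced line miR-301b-3p stood at 5.33 and 9.93 CPM (A and B), which rest on few counts. miR-143-3p rose by 2.78 ± 0.20 (edgeR adjusted p = 4.02e-06), let-7e-5p by 2.82 ± 0.35 (edgeR adjusted p = 0.000274) and miR-99b-5p by 1.24 ± 0.18 (edgeR adjusted p = 0.000732). miR-19a-5p fell by 2.06 on the log2 scale (edgeR adjusted p = 0.00404). The 136 calls became 57 (49 higher and 8 lower) without uninduced line A, 75 (56 and 19) without uninduced B, 78 (69 and 9) without induced A and 69 (62 and 7) without induced B, and 63 (54 and 9) with every library thinned to the smallest. More miRNAs were lower in other fits: 114 were higher and 89 lower with only the 2 groups in the fit, 126 and 75 without the knockout libraries, 116 and 77 when the letters A and B were added to that fit as a block, and 83 and 64 without TMM factors.

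Of the 79 measured Dlk1-Dio3 members 42 rose with doxycycline and 3 fell, miR-136-5p, miR-299a-3p and miR-381-3p (44 up and 3 down adjusted over the list alone; median 0.95, camera adjusted p = 3.22e-08, and adjusted p = 0.514 with an estimated correlation). In the miR-130 and miR-301 family 5 of 8 rose, the same 5 that fell in the knockout (5 up and 0 down adjusted over the list alone; median 1.85, camera adjusted p = 0.00655, and adjusted p = 0.514 with an estimated correlation). The let-7 family had 4 of 11 higher, let-7a-5p, let-7e-5p, let-7f-5p and let-7g-5p (4 up and 0 down adjusted over the list alone), and the list was not called (camera adjusted p = 0.0991). It was called as higher without wild type A (camera adjusted p = 0.0439) or B (0.0457), knockout 2 (0.0499) or uninduced line A (0.0403). The blood cell markers, with miR-150-3p and miR-150-5p of 5 lower (0 up and 3 down adjusted over the list alone; camera adjusted p = 0.0775), were not called. They were called as lower without wild type A (camera adjusted p = 0.0401) or B (0.0400), knockout 1 (0.0359) or 2 (0.0359) or uninduced line A (0.0395). The miR-15 and miR-16 family, with both arms of miR-195a of 12 lower (0 up and 2 down adjusted over the list alone; camera adjusted p = 0.0775), was not called. It was called as lower without wild type A (camera adjusted p = 0.0470) or B (0.0457), knockout 2 (0.0499), uninduced line B (0.0400) or induced line A (0.0298). Lists that fell were the miR-302-367 cluster, with miR-302a-3p, miR-302b-3p and miR-302d-5p of 5 lower (0 up and 5 down adjusted over the list alone; median -1.52, camera adjusted p = 0.0123, and adjusted p = 0.616 with an estimated correlation), and the miR-34 and miR-449 family, with both arms of miR-34a and miR-34c-5p of 6 lower (0 up and 6 down adjusted over the list alone; median -1.23, camera adjusted p = 0.0123, and adjusted p = 0.514 with an estimated correlation). miR-34a-5p fell by 1.13 on the log2 scale (edgeR adjusted p = 0.00581). In the miR-290-295 cluster 6 of 18 rose and 0 fell (7 up and 0 down adjusted over the list alone; camera adjusted p = 0.544). With 1 library left out, calls were lost (edgeR adjusted p in parentheses) for miR-130a-3p without uninduced A (0.139), uninduced B (0.320), induced A (0.174) or induced B (0.168), miR-301b-5p without uninduced A (0.0536), let-7a-5p without uninduced A (0.0564) or uninduced B (0.0516), and let-7g-5p without uninduced A (0.127), uninduced B (0.0566) or induced A (0.0976). The same held for miR-150-3p without uninduced A (0.0724), uninduced B (0.0855), induced A (0.173) or induced B (0.140). miR-150-5p lost its call without any 1 of these 4 libraries (edgeR adjusted p of at most 0.236). The same held for miR-195a-3p without uninduced A (0.0562), induced A (0.0730) or induced B (0.112), and miR-195a-5p without uninduced A (0.107) or induced B (0.147). It also held for miR-302a-3p without uninduced A (0.0724), uninduced B (0.120), induced A (0.145) or induced B (0.138), miR-302b-3p without uninduced A (0.181), uninduced B (0.107), induced A (0.0669) or induced B (0.307), and miR-302d-5p without uninduced A (0.123) or induced B (0.0746). In the miR-34 and miR-449 family it held for miR-34a-3p without uninduced A (0.390), induced A (0.193) or induced B (0.110), miR-34a-5p without induced A (0.0734) or induced B (0.0722), and miR-34c-5p without uninduced A (0.212), induced A (0.0665) or induced B (0.147). In the Dlk1-Dio3 cluster it held for miR-136-5p without uninduced A (0.472), induced A (0.103) or induced B (0.366), and miR-381-3p without uninduced A (0.233), uninduced B (0.0621), induced A (0.210) or induced B (0.112). None of the samples is a doxycycline-treated line without the AGO1 transgene, so the drug and AGO1 cannot be separated.

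**Figure D2:**
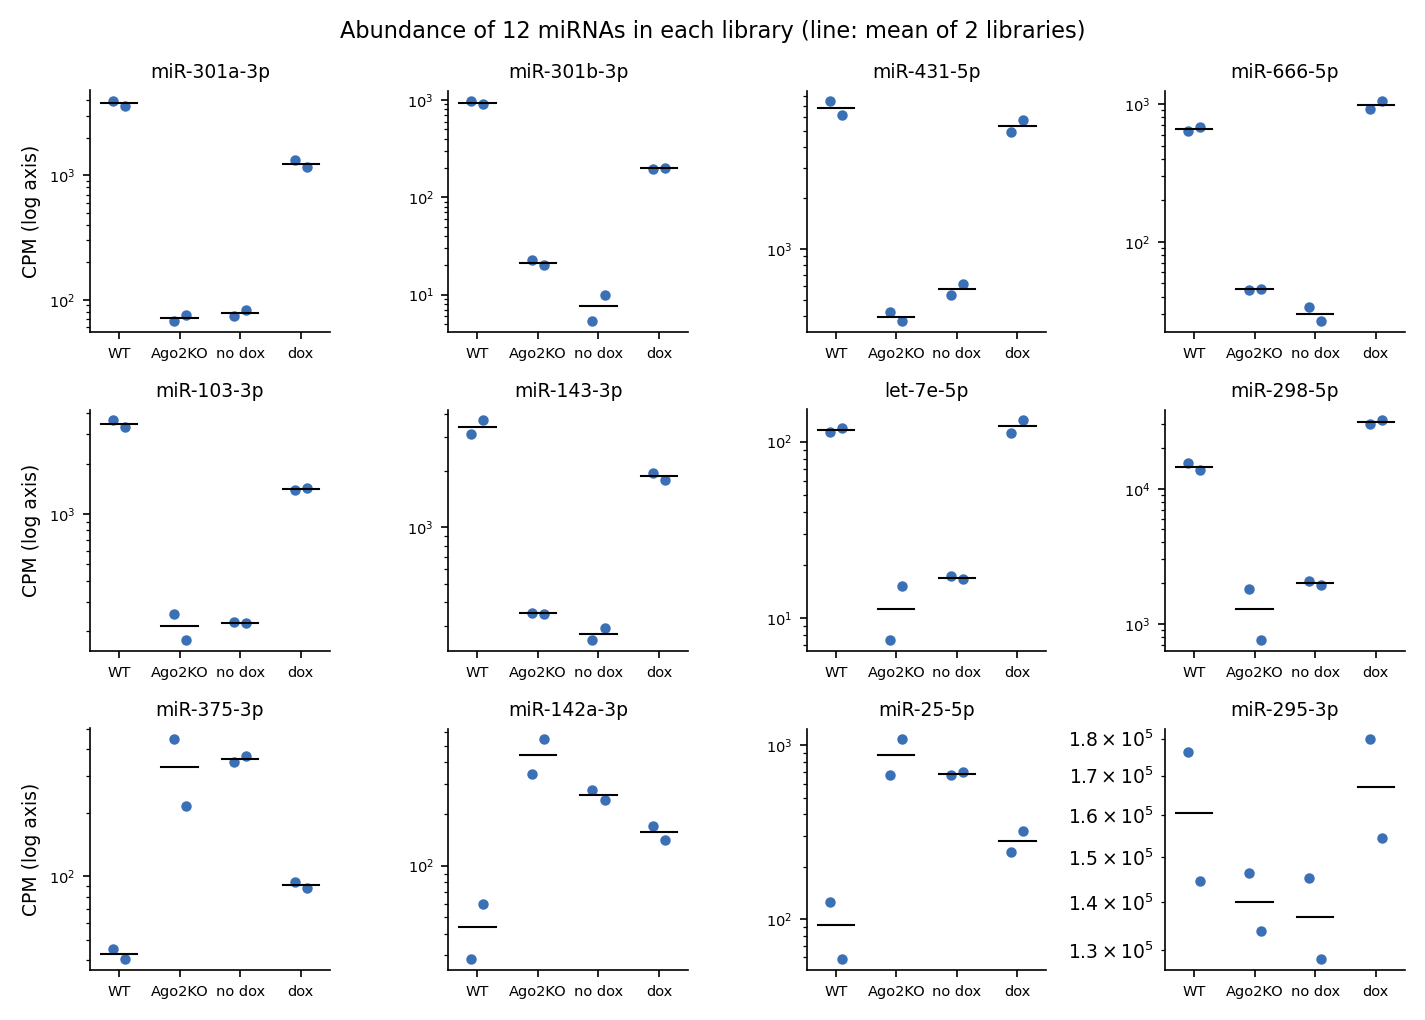
Abundance of 12 named miRNAs in each library (CPM, log axis); points are single libraries of wild type, knockout, and AGO1 line without and with doxycycline, and lines are means of 2 libraries. miR-301a-3p lies near 3784 CPM in wild type, 71.4 in the knockout, 78.7 without and 1240.1 with doxycycline.

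Changes with doxycycline ran opposite to those of the knockout. Of the 153 miRNAs lower in the knockout, 90 rose with doxycycline (32.2 by independent lists), miR-30e-5p fell and 62 were not called, with a median log2 fold change of 1.25. The 201 miRNAs not called in the knockout had a median of -0.13 with doxycycline. Of the 121 higher in the knockout, 23 fell (9.17 by independent lists), and the remaining 98 were not called, with a median of -0.61. Across the 475 miRNAs, which are not independent replicates, the log2 fold changes of the comparisons correlated with Pearson r = -0.74 and Spearman rho = -0.73 (covariance -1.96), and 74.9% had opposite signs. The comparisons share no library. The calls of miR-30e-5p were lost (edgeR adjusted p in parentheses) in the knockout without wild type A (0.0856) and with doxycycline without uninduced A (0.322), uninduced B (0.0812), induced A (0.305) or induced B (0.180). The slope of the doxycycline change on the knockout change was -0.55. More miRNAs were called in the same direction in both comparisons when either knockout library was left out, and such calls were absent with any other library left out. The 90 and 23 became 47 and 7 without uninduced line A (12.5 and 1.81 by independent lists), 50 and 15 without uninduced B (14.8 and 4.26), 57 and 9 without induced A (2.16 by independent lists for the 9), and 53 and 6 without induced B (13.7 and 1.66). They became 90 and 45 without knockout 1 (35.0 and 15.7), 99 and 46 without knockout 2 (37.1 and 16.9), 61 and 20 without wild type A (16.8 and 4.96), and 78 and 18 without wild type B (23.4 and 4.65).

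**Figure D3:**
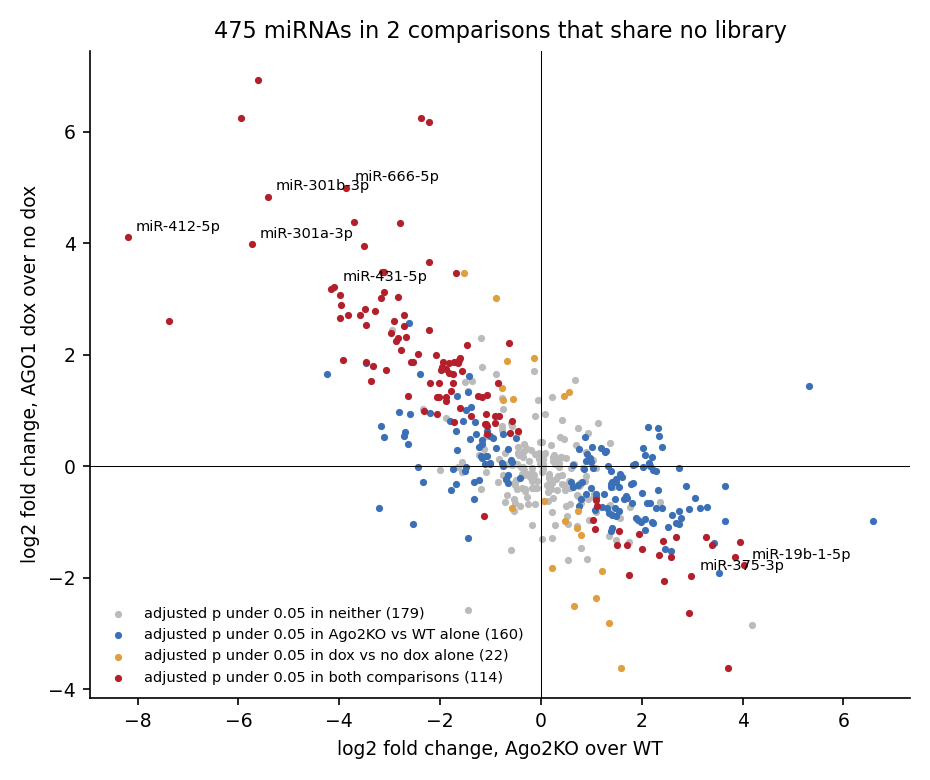
Log2 fold change with doxycycline in the AGO1 line (vertical) against log2 fold change of the knockout over wild type (horizontal) for 475 miRNAs, coloured by the comparison in which the edgeR adjusted p is under 0.05. Of the 114 miRNAs called in both, 90 lie at the upper left and 23 at the lower right.

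The uninduced AGO1 line was compared with the knockout lines to see what its derivation and puromycin selection changed before induction. miR-301a-3p stood at 71.4 ± 5.84 CPM in the knockout and 78.7 ± 5.75 CPM in the uninduced line, miR-143-3p at 349 ± 2.74 and 272 ± 27.9 CPM, and miR-375-3p at 331 ± 162 and 359.9 ± 15.3 CPM (n = 2 each). The edgeR quasi-likelihood test called 0 of 475 miRNAs (smallest adjusted p = 0.135), with 72 at an unadjusted p under 0.05, and DESeq2 called 8. Without knockout 1 edgeR called 61 miRNAs and without knockout 2 it called 33. The knockout lines are separate lines, and the labels derive the AGO1 line from line 1.

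As lists, the miR-17-92 cluster and paralogs (median -0.34, camera adjusted p = 0.000778), the miR-200 family (-0.72, camera adjusted p = 0.000752) and the Sfmbt2 cluster (-0.44, camera adjusted p = 0.000818) were lower in the uninduced line. With an estimated correlation these 3 came to adjusted p = 0.647, 0.437 and 0.770 by camera, in that order. Higher were the Dlk1-Dio3 cluster (0.20, camera adjusted p = 0.00833), the miR-99, miR-100 and miR-125 group (0.59, camera adjusted p = 0.00780), the X-linked germline cluster (0.29, camera adjusted p = 0.0166), the miR-34 and miR-449 family (0.50, camera adjusted p = 0.0418) and the miR-302-367 cluster (0.63, camera adjusted p = 0.0469). With an estimated correlation the X-linked cluster came to adjusted p = 0.770 and the other 4 of these to adjusted p = 0.647 by camera. Adjusted over the list alone, the counts were 4 up and 1 down in the miR-99, miR-100 and miR-125 group, 2 down in the miR-200 family, 1 down in the miR-17-92 list, 1 up in the miR-34 and miR-449 family and 0 in the other 4 by edgeR. Without knockout 2 the calls ended for the Dlk1-Dio3 (camera adjusted p = 0.599), Sfmbt2 (0.945), X-linked (0.827) and miR-302-367 lists (0.832). Without knockout 1 they ended for the miR-34 and miR-449 (camera adjusted p = 0.493) and miR-99, miR-100 and miR-125 lists (0.356). Without uninduced line A they ended for the Dlk1-Dio3 (camera adjusted p = 0.0574), X-linked (0.0649), miR-302-367 (0.0649) and miR-34 and miR-449 lists (0.118). The miR-302-367 call also ended without uninduced line B (camera adjusted p = 0.0873) and without wild type B (camera adjusted p = 0.0503). The miR-181 family was called as higher only without knockout 1 (camera adjusted p = 0.0441, and adjusted p = 0.229 with all libraries).

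The induced AGO1 line was compared with wild type to see what still differed once AGO1 was induced. miR-301a-3p stayed lower, at 1240.1 ± 115 CPM against 3784 ± 202 CPM in wild type (-1.61 ± 0.18, edgeR adjusted p = 0.000191). miR-363-3p, of the X-linked miR-106a-363 paralog of miR-17-92, was lower (-3.12 ± 0.32, edgeR adjusted p = 0.000112), as was miR-101b-3p (GRCm38 chromosome 19, 29135279 to 29135375, an intron of Rcl1), at -3.40 ± 0.35 (edgeR adjusted p = 0.000112). miR-181c-5p stood at 3064 ± 56.8 CPM in wild type, 533 ± 28.1 CPM without and 527 ± 20.4 CPM with doxycycline (-2.54 ± 0.18 against wild type, edgeR adjusted p = 2.63e-05). let-7e-5p, at 122 ± 13.8 CPM against 116 ± 4.22 CPM, was not called (0.07 ± 0.27, edgeR adjusted p = 0.848).

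In all, 91 miRNAs were higher and 94 lower than wild type by the edgeR quasi-likelihood test, 69 and 74 of them by at least 2-fold. miR-150-3p (3.23 ± 0.51, edgeR adjusted p = 0.00117) and miR-146a-5p (2.80 ± 0.48, edgeR adjusted p = 0.00184), both known from immune cells, were among the higher ones. The X-linked germline cluster was higher, with miR-465a-3p, miR-465c-3p, miR-465c-5p, miR-743b-3p and miR-871-5p of 10 called up (7 up and 0 down adjusted over the list alone; median 1.70, camera adjusted p = 0.0102, and adjusted p = 0.893 with an estimated correlation). Its share of all counts was 0.0255 ± 0.0024% in wild type, 0.060 ± 0.072% in the knockout and 0.0764 ± 0.0026% in the induced line (SD, n = 2). Its miR-871-3p stood at 339 CPM in knockout 1 and 30.2 CPM in knockout 2. The labels derive the AGO1 line from knockout 1, so a trait of that line cannot be told apart from an effect of AGO2 loss here. The let-7 family was lower, with 8 of 11 down and let-7c-5p up (1 up and 8 down adjusted over the list alone; median -1.43, camera adjusted p = 0.0303, and adjusted p = 0.893 with an estimated correlation). The miR-200 family was lower, with both arms of miR-141, miR-200a-3p and miR-429-3p of 8 down (0 up and 4 down adjusted over the list alone; median -0.99, camera adjusted p = 0.0404, and adjusted p = 0.717 with an estimated correlation). The Dlk1-Dio3 cluster had 15 of 79 up and 9 down (15 up and 9 down adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.453). With 1 library left out, calls were lost (edgeR adjusted p in parentheses) for miR-465c-3p without wild type B (0.109), miR-465c-5p without wild type A (0.127), wild type B (0.158) or induced B (0.115), and miR-743b-3p without wild type A (0.127), induced A (0.0759) or induced B (0.154). The same held for miR-141-3p without wild type A (0.0571) or induced B (0.0887), miR-141-5p without wild type A (0.0719), wild type B (0.0724), induced A (0.0759) or induced B (0.177), miR-200a-3p without induced B (0.107), and miR-429-3p without wild type A (0.0519), induced A (0.0631) or induced B (0.0521). Lists called only with a library left out were, without wild type B, the Sfmbt2 list (higher, camera adjusted p = 0.0133) and the miR-17-92 list (lower, camera adjusted p = 0.0164). The blood cell markers and the miR-99, miR-100 and miR-125 group were called as higher without wild type B (camera adjusted p = 0.0471 and 0.0296) or induced line B (camera adjusted p = 0.0464 and 0.0395). The 185 calls became 102 (68 higher and 34 lower) without wild type A, 105 (44 and 61) without wild type B, 105 (68 and 37) without induced line A and 75 (48 and 27) without induced line B. Without the 2 shallowest libraries 165 were higher and 98 lower.

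Of the 153 miRNAs lower in the knockout, 68 were also lower than wild type in the induced line, 6 were higher and 79 were not called. For 60 of the 153, the miRNA rose with doxycycline and was not called against wild type. Of the 121 higher in the knockout, 65 were also higher in the induced line and 56 were not called. These overlaps rest on the same wild type libraries. In 100 simulations of unchanged groups against them, the overlap averaged 0.03 with a maximum of 2. Unchanged groups give few calls, so this overlap cannot say how much the shared libraries add to the observed ones. The simulated correlation averaged 0.362 and the covariance 0.116, while the observed correlation was 0.633 and the covariance 1.45. Independent lists of the same sizes would share 30.3 lower and 23.2 higher miRNAs. With 1 wild type library for each comparison, chosen after the data were seen, no control library is shared. Both wild type libraries are still E14 cells, and the labels derive the AGO1 line from knockout 1. A difference of that line from E14 would therefore enter both comparisons and add to the overlap, which this split cannot remove. Wild type B for the knockout and A for the induced line gave 33 miRNAs lower in both (10.7 by independent lists) and 32 higher (9.26), with a correlation of 0.574 and a covariance of 1.46 over 494 miRNAs. The other way round gave 23 (8.60) and 37 (11.4), with 0.551 and 1.41. With 1 library left out of both comparisons the 68 and 65 became 23 and 50 without wild type A (6.15 and 14.1 by independent lists), 41 and 32 without wild type B (15.5 and 7.30), 27 and 49 without induced line A (8.59 and 16.3), and 22 and 39 without induced B (5.96 and 11.4). The 60 became 33 without uninduced line A, 34 without uninduced B and 39 without knockout 1. The 6 became 0 without wild type A or induced B, 1 without wild type B, 3 without induced A or either uninduced library, 18 without knockout 1 and 15 without knockout 2.

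A miRNA hairpin yields 2 mature arms, of which the major arm is usually the one loaded and the minor arm is mostly degraded. Over 139 hairpins with both arms measured, the median share of counts on the minor arm was 14.9 ± 0.38% in wild type, 17.9 ± 0.77% in the knockout, 18.7 ± 0.41% in the uninduced and 16.3 ± 0.47% in the induced AGO1 line (SD, n = 2). The minor arm is the one with the lower mean CPM over the 8 libraries, which in 14 of the 139 hairpins was the larger arm in wild type. The difference between knockout and wild type was 2.95 points, and 6.03 over hairpins of at least 100 CPM. These median shares are described without a test; the smallest p an exact test of 2 against 2 libraries can give is 0.333. As a list, the minor arms had 39 members higher and 34 lower in the knockout (38 up and 34 down adjusted over the list alone; camera adjusted p = 0.269). Summed over the hairpins the minor arms held 8.02, 9.02, 7.21 and 6.76% of counts in the same order of groups.

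The ratio of the arms was then tested within each hairpin, a test chosen after the data were seen, as were the hairpins named here. Between knockout and wild type the ratio differed in 58 of 139 hairpins by edgeR, with the minor arm gaining in 38 and losing in 20. Setting the minor arm by wild type counts alone gave 48 and 10, and by knockout counts 36 and 22; each of these uses 1 of the groups compared, so selection enters the split. In miR-25 of the miR-17-92 paralogs the log2 ratio of minor to major arm rose by 3.39 ± 0.39 (edgeR adjusted p = 1.37e-05). It rose by 3.01 ± 0.33 in miR-27b (edgeR adjusted p = 9.39e-06) and by 2.80 ± 0.45 in miR-182 (edgeR adjusted p = 0.000210). It fell in miR-30e (-2.69 ± 0.26, edgeR adjusted p = 3.79e-06). In miR-181c the ratio of 5p to 3p fell (-3.42 ± 0.23, edgeR adjusted p = 8.72e-08), where 5p is the smaller arm over the 8 libraries and held 67.7% of the counts in wild type. In this hairpin (GRCm38 chromosome 8, 84178873 to 84178961, an intron of Nanos3), the 5p arm fell from 3064 ± 56.8 to 566 ± 53.8 CPM while the 3p arm rose from 1464 ± 127 to 2869 ± 262 CPM.

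**Figure D4:**
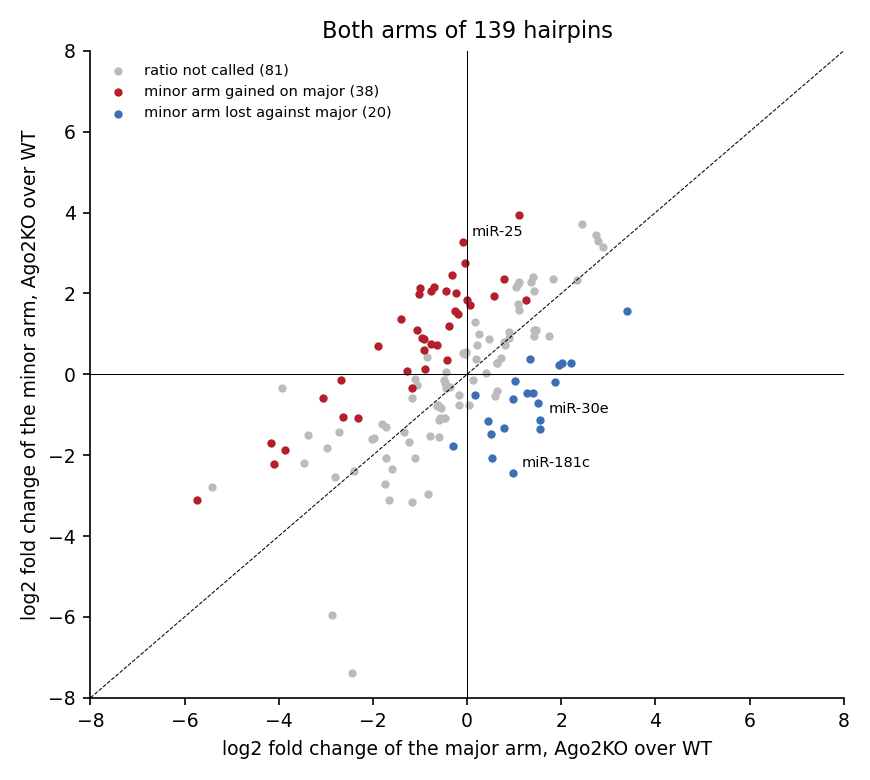
Log2 fold change of the minor arm (vertical) against the major arm (horizontal), set by mean CPM over the 8 libraries, knockout over wild type, for 139 hairpins; red marks hairpins whose minor arm gained on the major arm and blue those whose minor arm lost, at an edgeR adjusted p under 0.05 for the ratio, and the dashed line marks equal change. The 38 red points lie above that line and the 20 blue points below it.

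With doxycycline the ratio changed in 7 hairpins. It fell in miR-666 (-3.16 ± 0.47, edgeR adjusted p = 0.00146), miR-434, miR-136, miR-19a, miR-96 and miR-363, and rose in miR-3071 (3.58 ± 0.63, edgeR adjusted p = 0.00351). Between uninduced line and knockout it differed in 1 hairpin, miR-433 (-3.98 ± 0.75, edgeR adjusted p = 0.0163). Between induced line and wild type it differed in 66. Of the 58 hairpins called in the knockout, 6 were called in the opposite direction with doxycycline and 0 in the same direction by edgeR, where 33 of the 139 had an unadjusted p under 0.05 with doxycycline. A difference of knockout 1 from E14 would again enter both the knockout and the induced line's comparison with wild type. For 41 of the 58 (14.0 by independent lists), the ratio also differed from wild type in the same direction in the induced line, against the same wild type libraries. With 1 wild type library for each comparison it was 31 (9.63) with B for the knockout and A for the induced line, and 33 (10.9) the other way round. Across the 139 hairpins the ratio changes of knockout over wild type and of doxycycline correlated with Pearson r = -0.44 and Spearman rho = -0.44. The 7 hairpins with doxycycline, and the 6 of them opposite to the knockout, became 4 and 4 without uninduced line A, 2 and 2 without uninduced B, 3 and 3 without induced A, 0 and 0 without induced B, 17 and 11 without wild type A, 17 and 12 without wild type B, 23 and 16 without knockout 1, and 23 and 11 without knockout 2. The count in the same direction became 1 without either knockout library. The 66 became 39 without induced A, and the 1 became 0 without knockout 1 or uninduced A and 2 without knockout 2, wild type A or wild type B.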

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

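The alternatives added after the data were seen, namely the fits without the 2 shallowest libraries and with thinned counts, those of the arm ratio, and the minor arm set by wild type counts, are part of what follows. Over the planned and added alternatives, 1494 of 1687 values for named miRNAs kept direction and side of the threshold, 159 lost the call, 32 gained one and 2 reversed. For miR-22-3p Ago2KO vs WT, library totals gave 0.30 (edgeR adjusted p = 0.0468) in place of -0.01. For miR-871-5p Ago2KO vs WT, leaving out knockout 1 gave -5.56 (edgeR adjusted p = 0.145) in place of 2.29, and over the libraries left out the value ran from -5.56 to 3.05. Calls kept in every fit with 1 library left out were 151 of 274 for knockout against wild type, 44 of 136 for doxycycline and 59 of 185 for induced line against wild type. In the first, 4 called miRNAs changed sign: miR-129-1-3p (-0.16), miR-181a-5p (-0.51) and miR-871-5p without knockout 1, and miR-690 (-1.51, edgeR adjusted p = 0.0416) without knockout 2. In these fits the library left out came from 1 of the 2 groups compared. A lone library in a group was assumed to vary like the other groups. Pseudocounts were not run, since the table holds counts. The smallest library, at 163467 counts, limits what could be detected for rare miRNAs.

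With 1 library left out, counts of calls ran from 195 to 274 for knockout against wild type, 57 to 78 for doxycycline, 0 to 61 for uninduced line against knockout, and 75 to 105 for induced line against wild type. The correlation of the knockout and doxycycline changes ran from -0.72 to -0.59, the number of list calls from 19 to 25 (21 of 84 as reported), the minor arm share difference from 2.41 to 3.49 points for the knockout and -2.72 to -2.05 for doxycycline, and the arm ratio calls for the knockout from 43 to 56. Thinning every library to the smallest total gave 167, 63 and 95 calls for knockout, doxycycline and induced line against wild type, and a correlation of -0.81; fewer counts per miRNA are built into that alternative. Uninduced line against knockout, with 0 calls by edgeR and 72 at an unadjusted p under 0.05, gave 2 with library totals, 8 with DESeq2, 14 without a filter and 25 without the 2 shallowest libraries. The correlation was -0.82 with a mean CPM of at least 20, -0.79 over the miRNAs called in the knockout alone, and -0.58 without the 2 shallowest libraries. List calls fell to 0 by camera with an estimated correlation. The minor arm share difference of the knockout was 2.95 points, 6.03 over hairpins of at least 100 CPM and 3.40 with the minor arm set by wild type counts. Except for thinning, the cause was not tested.

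The letters A and B as a replicate block, in the 6 libraries that carry them, gave 193 calls for doxycycline and 250 for induced line against wild type, where the same 6 libraries without the block gave 201 and 255, and left the correlation at -0.74. The pairing check, the correlation of A minus B between groups over 385 miRNAs, gave 0.175 for wild type with uninduced line, -0.04 for wild type with induced line and 0.292 for uninduced with induced line. As 1 of these is under 0.1, the letters were not taken as pairs in any comparison. That value is for wild type with induced line. For doxycycline the relevant value is 0.292, so a pairing of uninduced with induced libraries stays open. The labels do not say what an A or B library shares with another. The block moved none of these counts of calls by over 1.5 times.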

Other observations

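The tests of this part chosen only after the result was seen are the comparison of medians at 1.38, the difference of arm medians at 0.29, the arm ratio at 58 hairpins, the fits without the 2 shallowest libraries and with thinned counts, the arms set by 1 group, and the choice of arms named here. In the knockout, arms from the miR-17-92 cluster and paralogs moved in both directions. miR-93-5p (edgeR adjusted p = 0.00129), miR-106b-5p (-1.23 ± 0.23, edgeR adjusted p = 0.00161), which share a proliferation-linked seed, and miR-363-3p (-3.07 ± 0.33, edgeR adjusted p = 4.51e-05) fell, and each is the more abundant arm of its hairpin. Less abundant arms went both ways. Among those that rose were miR-93-3p (2.14 ± 0.50, edgeR adjusted p = 0.00544), miR-25-5p (3.27 ± 0.37, edgeR adjusted p = 7.89e-05) and miR-19b-1-5p (4.02 ± 0.59, edgeR adjusted p = 0.000361). miR-106b-3p (-1.68 ± 0.27, edgeR adjusted p = 0.000744) and miR-18b-3p (-1.06 ± 0.35, edgeR adjusted p = 0.0271) fell, the latter not called without wild type A (edgeR adjusted p = 0.183) or knockout 1 (0.273). Over all 139 hairpins both arms were called in the same direction in 38 and in opposite directions in 11. The arm larger in wild type was the lower one in 10 of the 11, and the arm larger over the 8 libraries in 8. With each of the 4 libraries left out in turn, miR-181c, miR-182, miR-27b and miR-93 kept both opposite calls each time. The other 7 lost 1 or both: without wild type A miR-17-5p (0.0574), miR-20b-5p (0.276), miR-26b-5p (0.219), miR-290a-5p (0.267), miR-30e-5p (0.0856), miR-434-3p (0.0616) and miR-673-5p (0.0895); without wild type B miR-17-3p (0.205), miR-26b-3p (0.203), miR-290a-3p (0.155), miR-290a-5p (0.0502) and miR-434-5p (0.238); without knockout 2 miR-17-3p (0.0668) and miR-290a-5p (0.0809); without knockout 1 miR-26b-5p (0.0597), miR-26b-3p (0.374) and miR-434-5p (0.155) (edgeR adjusted p in parentheses).

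The 2 knockout libraries differed more from each other than those of the other groups. Over the counted miRNAs the Spearman correlation between the libraries of a group was 0.879 in the knockout, 0.972 in wild type, 0.969 in the uninduced and 0.981 in the induced line. Some miRNAs differed widely. miR-2137 stood at 32.4 CPM in knockout 1 and 20842 CPM in knockout 2, at 2981 and 15743 CPM in the uninduced line, at 1328 and 1254 CPM in the induced line and at 85.6 and 1053 CPM in wild type. miR-690 stood at 9.97 and 710.0 CPM in knockout lines 1 and 2. miR-871-3p, of the X-linked germline cluster, stood at 339 and 30.2 CPM in them. Knockout 2 is the shallowest library, at 163467 counts, and uninduced line B is the next, at 292895. In uninduced B miR-690 stood at 708 CPM, against 192 CPM in uninduced A. It stood at 49.7 and 186 CPM in induced A and B, and at 19.0 and 38.7 CPM in wild type A and B. Such spread was thus not limited to the knockout.

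Of the 153 miRNAs lower in the knockout, 90 rose with doxycycline, 1 fell and 62 were not called. Unequal depth alone is not enough to give this: with every library thinned to the smallest total the correlation of the changes was -0.81, and without the 2 shallowest libraries it was -0.58. The knockout and uninduced libraries were shallower than the wild type and induced ones, however. Thinning equalizes counts only, so other differences between libraries that go with depth cannot be told apart from the reversal. A drug or growth effect cannot be told apart from one of AGO1, as no treated line without the transgene is among the samples, and the 1.38 by which the lowered miRNAs exceeded those not called in median log2 fold change with doxycycline restates the pattern. Whether AGO1 may keep the same miRNAs from being lost that AGO2 keeps was not tested, and 68 of the 153 were also lower than wild type in the induced line. Clonal differences between wild type and knockout lines, which the drug would then have to offset, also stay open.

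In the knockout, the arms of a hairpin tended to change together, with r = 0.59 across 139 hairpins, which is consistent with altered amounts of some precursors. Precursor amounts alone do not account for the whole, since the ratio of the arms differed from wild type in 58 of 139 hairpins. A loss limited to the loaded arm cannot be told apart from other patterns by these medians. Major arms lay below minor arms by 0.29 with arms set over the 8 libraries, by 0.80 with arms set in wild type, which favours falls by selection, and by 0.30 with arms set in the knockout, which works against them. Another Argonaute with other arm preferences may hold the arms that gained; this was not tested, and no AGO pull-down was analysed here. Reads shared between near-identical miRNAs such as the miR-181 and miR-17 relatives stay open as well.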
